A study of Homo sapiens with 39 samples.

How the data were processed

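RNA of 39 human breast cancer cell lines was measured on 1-colour Affymetrix HG-U133A arrays, 1 array per line. Per the labels, the lines were grown in RPMI 1640 medium with 10% fetal bovine serum, and the medium was renewed 24 hours before lysis. RNA was purified on RNeasy columns, treated with DNase and checked on a Bioanalyzer, and 10 ug of total RNA went into each biotinylated cRNA preparation. The deposited values are probe set intensity on a linear scale, 1 value per probe set and array, made with GCOS 1.1 according to the submitters' processing notes. The notes state neither the summary algorithm nor the scaling target. The mean over the middle 96% of probe sets (2% left out at each end) was 200 within 5% on 33 arrays and outside that tolerance on 6 arrays, where it lay between 103 and 234. The scaling was therefore not common to all arrays.

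The table held 22283 probe sets, of which 68 controls were left out. Of the other 22215, 19065 were paired with 1 gene symbol, 1043 with several and 2107 with none listed. The gene identifiers of 19053 of the 19065 matched the reference gene table, which changed 0 symbols. Each of 11963 genes was represented by its probe set with the highest mean over the 39 arrays, and 4310 genes had more than 1 probe set. Values were analysed as log2 of the intensity plus 10, a pseudocount set from the median over arrays of the 20th percentile of intensity (10.2). The deposited scaling was kept. The table held 12 intensities of 0, and every column was used.

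Lines were grouped by the morphology in their labels, 13 as spindle and 21 as non-spindle. Morphology was not given for 5 lines (DU4475, HCC1937, MDA-MB-468, UACC812 and UACC893), which entered no test. Replicates were different cell lines, so each p-value measures a difference against the spread between lines and not against repeated cultures or arrays. No batch, date or culture replicate was recorded. The number of arrays and the distance of a signal from background limited the precision.

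Differences were spindle minus non-spindle, fitted with limma 3.58.1 (lmFit and eBayes) in R 4.3.3. A gene was called at a Benjamini-Hochberg adjusted p under 0.05 over the 11963 genes. The 22 gene lists were written from general knowledge before the data were examined, as were the comparisons, the tests, most alternatives and the rule for naming genes. They were tested against the other genes with camera at a preset correlation of 0.01, adjusted over the 22 lists, then with camera at an estimated correlation and with fry, whose p tests whether the genes of a list move, on balance, one way. Members were also adjusted over the list alone. Principal components of the centred values of the 34 compared lines were tested against morphology with two-sided permutation tests of 100000 resamples, as were 6 measures per array. CDH1 was correlated with 6 genes inside each morphology group (12 relations, Pearson and Spearman, permutation p). For these 12 relations no r was given where a gap wider than 0.333 of a gene's range had at least 3 lines on both sides. Other r values were not checked for such gaps. Python 3.11.15 with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9 did the permutation tests, counts and plots.

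The genes named were the 10 called genes with the largest difference in each direction, up to 3 called members of each list in each direction (in a list with no called member, the 2 largest differences as values) and a set of genes for adhesion, epithelial-mesenchymal transition (EMT) and receptor status fixed beforehand (CDH1, CDH2, CDH3, VIM, ZEB1, ZEB2, SNAI1, SNAI2, TWIST1, ESR1, ERBB2, EGFR, KRT5, KRT18, GATA3, FOXA1 and CTNNA1). XIST and Y-linked genes were left out. On simulated data with 50 changed genes at each size, the fit recovered 92% of genes at a log2 difference of 2 and of -2, 68% at 1 and 58% at -1, with 9 false calls. The simulated genes varied independently, with the same spread in both groups, and the changed ones had a mean above the median. Real spreads could be unequal, as for KRT19 (SD 3.96 in spindle and 0.58 in non-spindle lines), so these rates may not hold for the real calls. The alternatives set then were quantile normalization, scaling to the 75th percentile, pseudocounts of 1 and 40, only genes with a mean above the median, the mean of all probe sets of a gene, eBayes with trend and robust, array weights, the 3' to 5' signal ratio of the GAPDH and ACTB controls as a covariate, a Wilcoxon rank-sum test, omission of each line in turn, omission of MDA-MB-435s (whose tissue of origin is disputed) and, for the components, genes scaled to unit variance. Scaling each array to 1 trimmed mean, alone or together with an estimated correlation, and omission of the arrays off that mean were added after seeing the data.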

Results

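Gene expression was measured in 39 established human breast cancer cell lines grown as unperturbed cultures, with 1 HG-U133A array per line. The labels gave a spindle morphology for 13 lines and a non-spindle morphology for 21. Morphology was not stated for the other 5 lines. The median probe set intensity of an array ran from 35.5 in MDA-MB-435s to 76.1 in MDA-MB-157. The closest pair of lines, BT474 and MDA-MB-361, had a correlation of 0.930 across probe sets, which are not independent replicates. No line had a second array to show what r a duplicate would give, so whether any lines share an origin was not settled.

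The comparison of spindle with non-spindle lines addressed whether elongated, fibroblast-like growth in culture goes with loss of epithelial adhesion genes such as CDH1 (E-cadherin) and with expression of EMT genes. Spindle lines had lower values of genes for epithelial adhesion and luminal identity, and higher values of mesenchymal markers and of genes for extracellular matrix, the actin cytoskeleton and inflammatory cytokines. CDH1 itself separated the groups less completely than many of these genes. The basal keratin KRT5 and P-cadherin (CDH3) were not called as different, and neither were proteasome genes as a list.

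Of 11963 genes, 2232 (18.7%) were called, 954 higher and 1278 lower in spindle lines, and 574 and 590 of these differed by a log2 value of at least 1. Lower genes did not outnumber higher ones when every array was scaled to 1 trimmed mean, where 1222 were higher and 1158 lower, nor without MDA-MB-435s, where 1108 were higher and 1068 lower. Under the scalings set beforehand lower genes remained in excess. With quantile normalization 1111 were higher and 1286 lower, and with 75th percentile scaling 1124 and 1270. The arrays of 4 spindle lines (MDA-MB-435s, SUM1315MO2, Hs578T and MDA-MB-157) and 1 non-spindle line (MDA-MB-330) had a trimmed mean over 5% away from 200 and are termed off-target (Fisher's exact test, two-sided, p = 0.0586). The log2 ratio of 3' to 5' control signal, a measure of RNA integrity, was 0.13 ± 0.19 (SD, n = 13) in spindle and 0.35 ± 0.29 (SD, n = 21) in non-spindle lines (permutation p = 0.0191, adjusted p = 0.0381 over 6 array measures). The difference was -0.30 for the ACTB control (permutation p = 0.0139, adjusted p = 0.0381) and -0.15 for GAPDH (permutation p = 0.158, adjusted p = 0.237). Trimmed mean and median intensity were not called as different (adjusted permutation p = 0.458 and 0.537). The median correlation of a line with all other lines was 0.845 ± 0.0156 in spindle and 0.882 ± 0.00902 in non-spindle lines (permutation p = 1e-05, adjusted p = 6e-05). This measure tends to be lower in the smaller group when the groups differ, and it also depends on the spread inside each group. With the 3' to 5' ratio as a covariate, 1631 of the called genes (73.1%) were still called in the same direction.

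**Figure D1:**
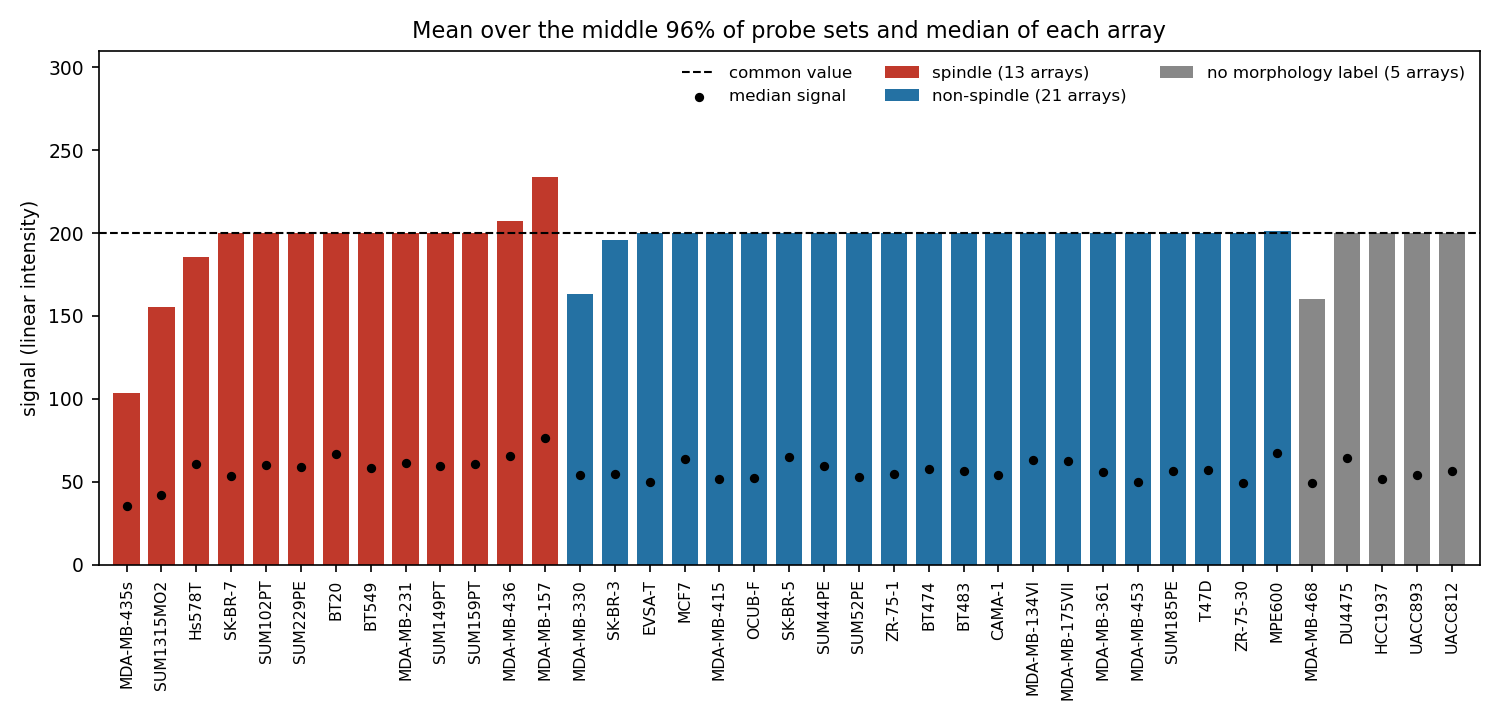
Trimmed mean (bars) and median (dots) of probe set intensity for each of the 39 arrays, by morphology, with a dashed line at 200. On 33 arrays the trimmed mean lay within 5% of the line, and the lowest bar was MDA-MB-435s at 103.

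The largest higher values were those of CAV1, the main structural protein of caveolae (log2 difference 6.70 ± 0.37 SE, adjusted p = 1.1e-15), VIM, the intermediate filament vimentin (5.83 ± 0.57), MSN, the membrane-to-actin linker moesin (5.73 ± 0.32), and CAVIN1, a caveolar coat protein (5.32 ± 0.36). FOSL1, an AP-1 transcription factor, followed with 5.17, then the hyaluronan receptor CD44 and EMP3 with 4.88 each, LDHB with 4.84, the lysyl oxidase family member LOXL2 with 4.74 and CAV2 with 4.66. All 13 spindle lines lay above all 21 non-spindle lines for CAV1, MSN, CAVIN1 and FOSL1, as did 12 for EMP3, LOXL2 and CAV2, 10 for VIM, 8 for CD44 and 4 for LDHB. The largest lower values were those of AGR2, a protein disulfide isomerase of secretory epithelium (-6.45 ± 0.64, adjusted p = 2.1e-09), and the simple-epithelium keratin KRT19 (-6.42 ± 0.83). After these came FXYD3 (-5.32), the mammary secretoglobin SCGB2A2 (-5.00), the selenium carrier SELENOP (-5.00), the adhesion molecule EPCAM (-4.65), the trefoil peptide TFF1 (-4.65), the protease inhibitor SPINT2 (-4.51), the apical recycling GTPase RAB25 (-4.49) and ADIRF (-4.45). For SELENOP all 13 spindle lines lay below every non-spindle line, whereas none did for SCGB2A2, which ranged from 3.45 to 13.09 in the non-spindle lines.

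In 22 genes the values of the groups did not overlap, 6 higher and 16 lower in spindle lines, and 21 of them also did not overlap after trimmed mean scaling. The highest count in any of the other random splits of the same lines was 0. The widest gaps belonged to CAV1, MSN and XBP1, a transcription factor of secretory and luminal cells (-3.46 ± 0.18, adjusted p = 1.5e-16). FOXA1, which opens chromatin for the estrogen receptor, had 5.48 ± 1.06 (SD, n = 13) in spindle and 9.45 ± 0.29 (SD, n = 21) in non-spindle lines. The other non-overlapping lower genes included the ETS factor SPDEF (-3.98), the receptor kinase ERBB3 (-3.88), the tight junction protein TJP3 (-2.78) and the prolactin receptor PRLR (-1.74), and the higher ones included the ectonucleotidase NT5E (4.21) and ACSL4 (2.81). These 6 genes were named after their values were seen.

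CDH1 had a log2 value of 5.95 ± 3.49 (SD, n = 13) in spindle and 9.83 ± 2.55 (SD, n = 21) in non-spindle lines, a difference of -3.88 ± 0.99 SE (adjusted p = 0.00438). Without the 5 off-target arrays the difference was -3.04 and was no longer called (adjusted p = 0.0809, in a range of 0.000996 to 0.0809 over 46 alternatives). That omission took out 4 spindle lines with CDH1 from 3.41 to 6.02 and 1 non-spindle line with 10.46. The call was lost in no other alternative, and whether scaling or the loss of these lines ended it was not tested. The second CDH1 probe set gave -1.53 (adjusted p = 0.0620 over probe sets). The CDH1 signal was under the pseudocount in 8 spindle lines and in 1 non-spindle line, SK-BR-3. In 3 spindle lines, SUM149PT, BT20 and SUM229PE, CDH1 was 11.08, 11.50 and 11.87, above the non-spindle median of 10.86. Among the non-spindle lines, ZR-75-30 (5.83), SUM44PE (6.64), MDA-MB-134VI (6.95), SK-BR-5 (6.98) and MDA-MB-453 (7.31) had low CDH1 besides SK-BR-3 (3.42). The next line, CAMA-1, had 9.55. CTNNA1, which ties the E-cadherin complex to actin, was 3.72 in MDA-MB-157 and 6.88 in MDA-MB-330, and between the groups it differed by -0.87 ± 0.46 (adjusted p = 0.207).

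Genes of epithelial adhesion and identity were lower as a group: 28 of 30 measured were lower and 2 were not called (29 lower when adjusted over the list alone), with a median log2 difference of -2.46 (camera adjusted p = 4.9e-27, adjusted p = 0.0166 with an estimated correlation). Examples were EPCAM, SPINT2 and RAB25, for which 11, 10 and 10 of the 13 spindle lines lay below every non-spindle line. Their highest spindle values (11.02, 11.82 and 10.17) lay inside the non-spindle ranges. Line medians over the list ran from 4.33 to 8.71 in spindle and from 8.07 to 9.07 in non-spindle lines. CDH1 was among the lower members. The cadherin and catenin list divided, with 3 of 18 genes higher, 3 lower and 12 not called (3 and 3 when adjusted over the list alone). The mesenchymal cadherins CDH11 (2.67 ± 0.49) and CDH2 (1.52 ± 0.32) and the catenin-like CTNNAL1 (1.49 ± 0.28) were higher, and CDH1, plakoglobin (JUP, -3.06 ± 0.51) and CTNND2 (-2.34 ± 0.30) were lower. As a group this list was not called (camera adjusted p = 0.913), its median was 0.03, its mean was -0.30 and the test pointed up. P-cadherin (CDH3) differed by -1.62 ± 0.84 (adjusted p = 0.194).

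**Figure D2:**
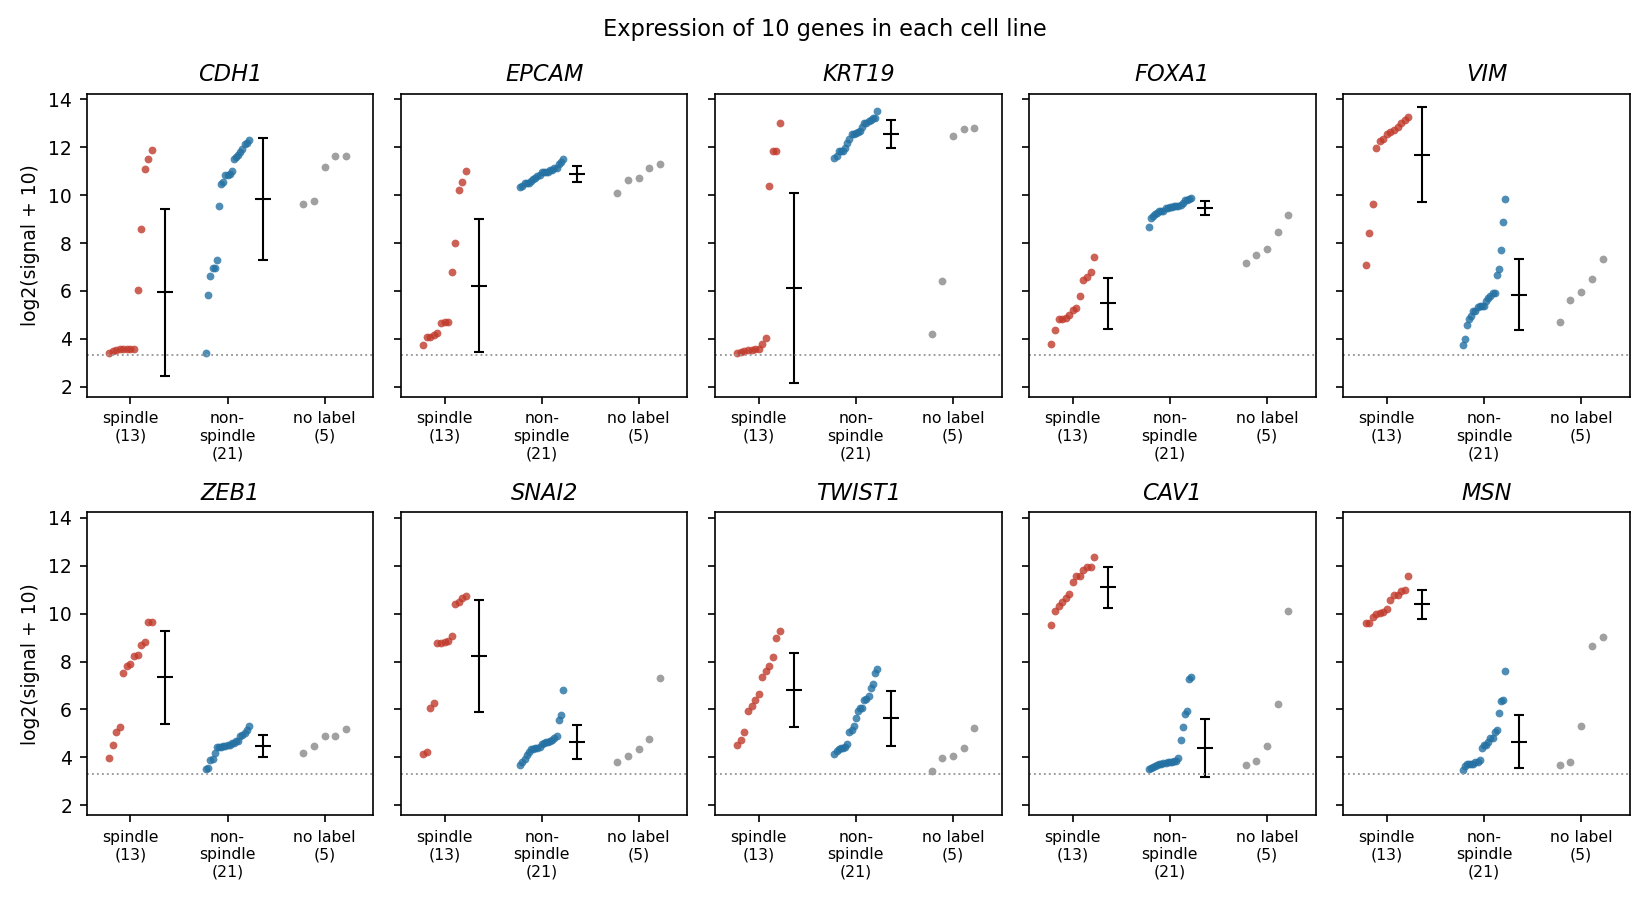
Log2 values of 10 genes in each line, with the mean ± SD of the 13 spindle and 21 non-spindle lines, the 5 lines of unstated morphology beside them, and a dotted line at the log2 of the pseudocount (3.32). CAV1, MSN and FOXA1 show no overlap between the morphologies, whereas CDH1 spans from background to over 11 in the spindle lines.

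Mesenchymal markers were higher as a group: 26 of 28 were higher and 2 were not called (26 when adjusted over the list alone), with a median log2 difference of 2.77 (camera adjusted p = 2.7e-30, adjusted p = 0.000512 with an estimated correlation). VIM, CAV1 and MSN stood among the highest. Of 11 EMT transcription factors, 5 were higher, 0 lower and 6 not called (7 higher when adjusted over the list alone), with a median of 0.74 (camera adjusted p = 0.000144, adjusted p = 0.0259 with an estimated correlation). This list was not called among the genes with a mean above the median (adjusted p = 0.865). However, SNAI2, ZEB1, ZEB2, TCF4, SNAI1 and TWIST1 were not above that median, so the test covered only remaining members. SNAI2, a repressor of epithelial genes, differed by 3.60 ± 0.52, the E-cadherin repressors ZEB1 and ZEB2 by 2.85 ± 0.42 and 1.28 ± 0.22, and TCF4 by 1.54 ± 0.42, which was not called without the off-target arrays (1.21, adjusted p = 0.0926). SNAI1 (0.48 ± 0.29, adjusted p = 0.281) and TWIST1 (1.19 ± 0.44, adjusted p = 0.0564) were not called, but the TWIST1 call depended on the setting. TWIST1 was called with quantile normalization (adjusted p = 0.0496), 75th percentile scaling (0.0438) and trimmed mean scaling (0.0409) and when any 1 of 7 lines was left out, most clearly without MDA-MB-231 (1.38, adjusted p = 0.0245). It was farthest from a call without the off-target arrays (adjusted p = 0.423).

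Inside the spindle group CDH1 and ZEB2 had Pearson's r = -0.794 (permutation p = 0.00188, adjusted p = 0.00928 over 12 relations; n = 13). Spearman's rho was -0.574 (permutation p = 0.0435, adjusted p = 0.522), and r was -0.621 without the 2 lines farthest from the ZEB2 median. Of these 13 lines, 8 had CDH1 under the pseudocount, and no r was given with quantile normalization or with pseudocounts of 1 and 40, where the lines fell into clusters. ZEB2 was also near background: its signal was under the pseudocount in BT20, SUM149PT, SK-BR-7 and MDA-MB-231, and its highest was 79.3 in Hs578T. CDH1 had r = 0.184 with SNAI1 (rho = 0.187, permutation p = 0.551 and 0.540, adjusted p = 0.690) and r = -0.474 with TWIST1 (rho = -0.245, permutation p = 0.103 and 0.418, adjusted p = 0.310). The spindle lines fell into clusters for ZEB1, SNAI2 and VIM, so no r was given for these 3. In the non-spindle lines r lay between -0.167 and 0.232 for all 6 genes (lowest adjusted permutation p = 0.690). Without the 2 lines farthest from the TWIST1 median, r with TWIST1 went from 0.153 to 0.503. ZEB2 was under the pseudocount in every non-spindle line, so its r there says little.

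Luminal epithelial markers were lower as a group, 26 of 29 being lower and 3 not called (27 lower when adjusted over the list alone), with a median of -2.52 (camera adjusted p = 1.9e-28, adjusted p = 3.4e-05 with an estimated correlation). AGR2, KRT19 and SCGB2A2 led this list. KRT18, a keratin of simple epithelia, was lower by a smaller amount (-2.35, adjusted p = 0.00661) and was not called without the off-target arrays (-1.69, adjusted p = 0.058). GATA3, a luminal lineage factor, was lower by a log2 difference of -3.29 ± 0.56. In the estrogen response list, which shares 6 genes with other lists, 14 of 22 were lower and 8 not called (15 lower when adjusted over the list alone), with a median of -1.13 (camera adjusted p = 1.0e-07, adjusted p = 0.0763 with an estimated correlation). TFF1, TFF3 (-4.39 ± 0.71) and XBP1 were its lowest members. The estrogen receptor gene ESR1, a member of the luminal list, differed by -2.87 ± 0.59 with the brightest of its 9 probe sets. None of its other probe sets was called (differences of -0.60 to 0.09, lowest adjusted p = 0.143 over probe sets). As the mean of its probe sets it was called at adjusted p = 0.0421. For the ERBB2 amplicon, 4 of 12 genes were lower and 8 not called (6 lower when adjusted over the list alone), with a median of -0.42 (camera adjusted p = 0.0123, adjusted p = 0.40 with an estimated correlation). ERBB2 differed by -2.46 ± 0.55, PGAP3 by -1.51 ± 0.34 and GRB7 by -1.63 ± 0.41, and GRB7 was not called without the off-target arrays (-1.27, adjusted p = 0.058). The second ERBB2 probe set gave -1.32 (adjusted p = 0.0979 over probe sets). Basal and myoepithelial markers had 5 of 23 genes higher, 0 lower and 18 not called (7 higher and 1 lower when adjusted over the list alone), with a median of 0.48 (camera adjusted p = 0.00122, adjusted p = 0.179 with an estimated correlation). The higher members included the growth factor receptor EGFR (3.75 ± 0.53), the calcium-binding S100A2 (3.04 ± 0.51) and the endopeptidase MME (2.67 ± 0.52), whereas the basal keratin KRT5 differed by 0.37 ± 0.58 (adjusted p = 0.729). KRT17, KRT6A, KRT6B and TP63 were not analysed here.

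**Figure D3:**
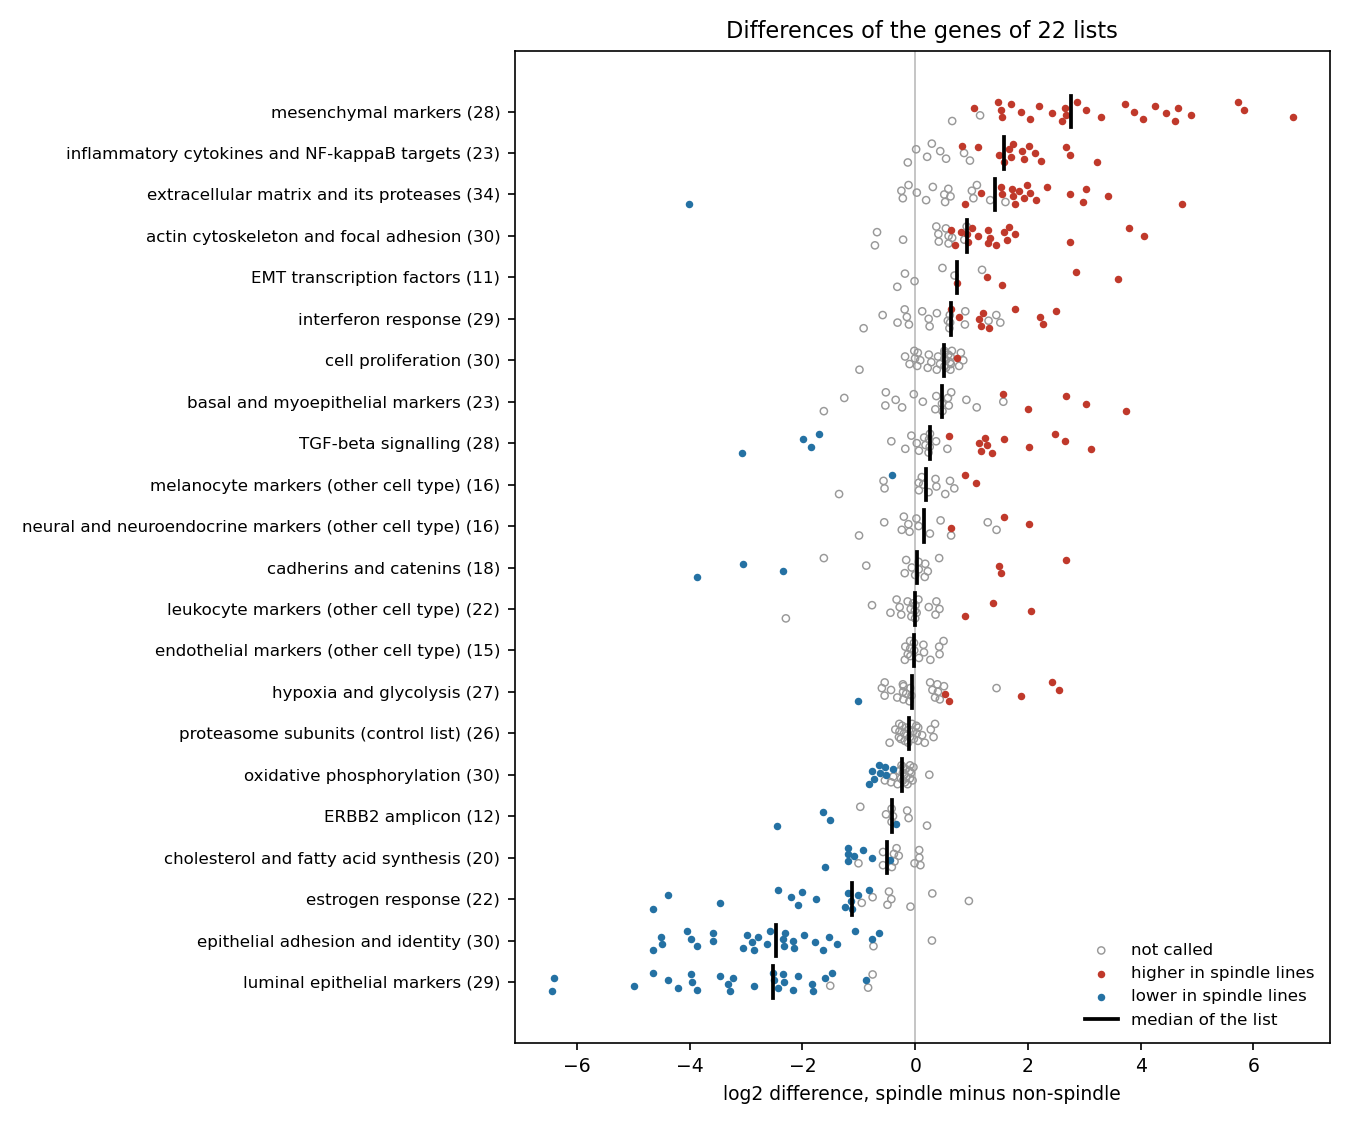
Log2 difference (spindle minus non-spindle) of each measured gene in the 22 lists, with a bar at the list median. Mesenchymal markers have the highest median (2.77) and luminal markers the lowest (-2.52).

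Matrix and cytoskeletal genes were higher as groups. In the extracellular matrix and protease list 18 of 34 genes were higher, 1 lower and 15 not called (21 and 1 when adjusted over the list alone), with a median of 1.42 (camera adjusted p = 3.4e-11, adjusted p = 0.0259 with an estimated correlation). The crosslinking enzyme LOXL2 and the collagens COL4A1 (3.42 ± 0.42) and COL6A1 (3.03 ± 0.44) were its highest members. The only lower member was the membrane metalloproteinase MMP14 (-4.01 ± 0.53), whose call rests on 1 of 4 probe sets: the other 3 gave 1.36, 2.75 and 1.78, and their mean with it gave 0.47 (adjusted p = 0.176, in a range of 1.9e-08 to 0.176 over 46 alternatives). Among actin and focal adhesion genes, 18 of 30 were higher, 0 lower and 12 not called (18 and 1 when adjusted over the list alone), with a median of 0.92 (camera adjusted p = 2.6e-11, adjusted p = 0.0166 with an estimated correlation). They included ANXA1 (4.07 ± 0.65), the myosin light chain MYL9 (3.80 ± 0.65) and the focal adhesion adaptor FHL2 (2.74 ± 0.64). The TGF-beta list moved both ways, with 11 of 28 genes higher, 4 lower and 13 not called (11 and 5 when adjusted over the list alone), and a median of 0.26 (camera adjusted p = 0.00215, adjusted p = 0.183 with an estimated correlation). The receptor TGFBR2 (3.11 ± 0.36), TGFB1I1 (2.65 ± 0.37) and the ligand TGFB1 (2.48 ± 0.40) were higher, and the activin subunit INHBB (-3.08 ± 0.46), the pseudoreceptor BAMBI (-1.99 ± 0.49) and the differentiation inhibitor ID2 (-1.84 ± 0.43) were lower. This list was not called among the genes with a mean above the median (adjusted p = 0.143).

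Inflammatory cytokine and NF-kappaB target genes were higher as a group, with 15 of 23 higher, 0 lower and 8 not called (17 higher when adjusted over the list alone) and a median of 1.58 (camera adjusted p = 7.6e-12, adjusted p = 0.0259 with an estimated correlation). The neutrophil-attracting chemokines CXCL2 (3.23 ± 0.49) and CXCL1 (2.75 ± 0.63) and the cytokine IL32 (2.67 ± 0.54) were the highest, and IL32 was not called by the Wilcoxon test (adjusted p = 0.146). Of 29 interferon response genes, 10 were higher, 0 lower and 19 not called (12 higher when adjusted over the list alone), with a median of 0.64 (camera adjusted p = 1.0e-05, adjusted p = 0.248 with an estimated correlation). The immunoproteasome subunits PSMB8 (2.51 ± 0.60) and PSMB9 (2.21 ± 0.34) and the GTPase GBP1 (2.27 ± 0.40) were higher.

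Metabolic and growth lists gave smaller differences. Of 20 cholesterol and fatty acid synthesis genes, 8 were lower and 12 not called (10 lower when adjusted over the list alone), with a median of -0.51 (camera adjusted p = 0.000515, adjusted p = 0.204 with an estimated correlation). Examples were the desaturase SCD (-1.61 ± 0.37, not called as the mean of its probe sets, adjusted p = 0.0617), the lipid synthesis regulator SREBF1 (-1.19 ± 0.26) and HMGCS1 (-1.19 ± 0.29). Of 30 oxidative phosphorylation genes, 8 were lower and 22 not called (8 lower when adjusted over the list alone), with a median of -0.23 (camera adjusted p = 0.00179, adjusted p = 0.416 with an estimated correlation). COX6C, a subunit of cytochrome oxidase, was lower (-0.77 ± 0.16). NDUFC1 was lower (-0.82 ± 0.20) but was not called without the off-target arrays (-0.58, adjusted p = 0.053). UQCRC2 was lower as well (-0.73 ± 0.25) but lost its call in 13 of 46 alternatives, among them the 3' to 5' covariate (-0.50, adjusted p = 0.209) and omission of any 1 of 8 lines (without BT20 -0.55, adjusted p = 0.0780). For cell proliferation, 1 of 30 genes was higher and 29 were not called (0 when adjusted over the list alone), with a median of 0.52 (camera adjusted p = 0.00118, adjusted p = 0.467 with an estimated correlation and 0.142 with fry). The higher gene was the checkpoint kinase BUB1 (0.73 ± 0.22). The hypoxia and glycolysis list was not called (camera adjusted p = 0.119), and its median (-0.07) differed in sign from its mean (0.27) and its test, with 5 of 27 higher, 1 lower and 21 not called (6 and 1 when adjusted over the list alone). It held the higher vasoactive peptide gene ADM (2.54 ± 0.38), the glucose transporter SLC2A3 (2.43 ± 0.46) and the phosphofructokinase PFKP (1.87 ± 0.38), and the lower prolyl hydroxylase EGLN3 (-1.01 ± 0.35, adjusted p = 0.042). EGLN3 lost its call in 22 of 45 alternatives, among them omission of the off-target arrays (-0.70, adjusted p = 0.302) and of any 1 of 17 lines (without SUM1315MO2 -0.91, adjusted p = 0.0777). None of 26 proteasome subunit genes, a control list, was called (0 when adjusted over the list alone, camera adjusted p = 0.671). The largest differences were those of PSMB3 (-0.45, adjusted p = 0.346) and PSMA2 (-0.35, adjusted p = 0.128), which was called as the mean of its probe sets (-0.57, adjusted p = 0.00763).

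Markers of other cell types were not called as groups over all genes. Of 16 melanocyte markers, 2 were higher, CSPG4 (1.09 ± 0.32) and MITF (0.89 ± 0.26), 1 was lower, PMEL (-0.41 ± 0.14), and 13 were not called (2 and 1 when adjusted over the list alone; median 0.19, camera adjusted p = 0.219). All 3 calls were lost in at least 1 alternative, CSPG4 without the off-target arrays (0.62, adjusted p = 0.173) and MITF with the 3' to 5' ratio as a covariate (adjusted p = 0.0648). In MDA-MB-435s, a line of disputed tissue of origin, 8 of the 16 markers had their highest value of all 39 lines, among them SOX10 (10.15, next highest 5.83), S100B (9.20, next 4.05) and MLANA (8.58, next 5.87). Of 22 leukocyte markers, 3 were higher and 19 not called (3 when adjusted over the list alone; camera adjusted p = 0.331), namely the Rho GTPase RAC2 (2.05 ± 0.47), EVI2B (1.38 ± 0.29) and LAPTM5 (0.89 ± 0.27). The Wilcoxon test did not call RAC2 (adjusted p = 0.118) or LAPTM5 (0.0809), and LAPTM5 was not called with the 3' to 5' covariate (0.0542). The median of this list was -0.00, and its mean and test were positive (0.05). None of 15 endothelial markers was called (0 when adjusted over the list alone; camera adjusted p = 0.425, median -0.02, mean 0.08 and an upward test), with LYVE1 at 0.50 (adjusted p = 0.0551, in a range of 0.0230 to 0.134 over 45 alternatives) and PECAM1 at 0.43 (adjusted p = 0.106). Of 16 neural and neuroendocrine markers, 3 were higher and 13 not called (3 when adjusted over the list alone; median 0.16, camera adjusted p = 0.105), namely the granins SCG5 (2.01 ± 0.60) and SCG2 (1.57 ± 0.43) and the tubulin TUBB3 (0.64 ± 0.18). With the 3' to 5' covariate SCG5 (adjusted p = 0.0778) and TUBB3 (0.0712) were not called, nor was SCG5 by the Wilcoxon test (0.197). The neural list was called among the genes with a mean above the median (adjusted p = 0.0349).

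The main axis of variation among the 34 compared lines separated the morphologies. The first component held 20.8% of the variance, with scores of 49.0 ± 18.03 (SD, n = 13) in spindle and -30.3 ± 5.49 (SD, n = 21) in non-spindle lines (permutation p = 1e-05, the smallest that the resamples can give, adjusted p = 2e-05 over 2 components). Spindle scores ran from 13.8 (BT20) to 74.1 (Hs578T) and non-spindle scores from -39.2 to -17.6 (MCF7). After BT20, the spindle lines nearest the non-spindle group were SUM229PE (16.4) and SUM149PT (35.0), and these 3 were the lines with CDH1 above the non-spindle median. In the same 3 lines KRT19 lay between 11.83 and 12.99 and ZEB1 between 3.97 and 5.06. The second component held 5.64% of the variance and did not differ by morphology (difference -4.49, permutation p = 0.564). Its highest scores were those of MDA-MB-435s (64.9) and SUM1315MO2 (38.5), whose arrays had the lowest trimmed means (103 and 155), whereas MDA-MB-330, at 163, scored 8.75. Spindle scores on it ran from -35.6 to 64.9, but from -45.8 to 25.9 after trimmed mean scaling, so this axis depended on the scaling.

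**Figure D4:**
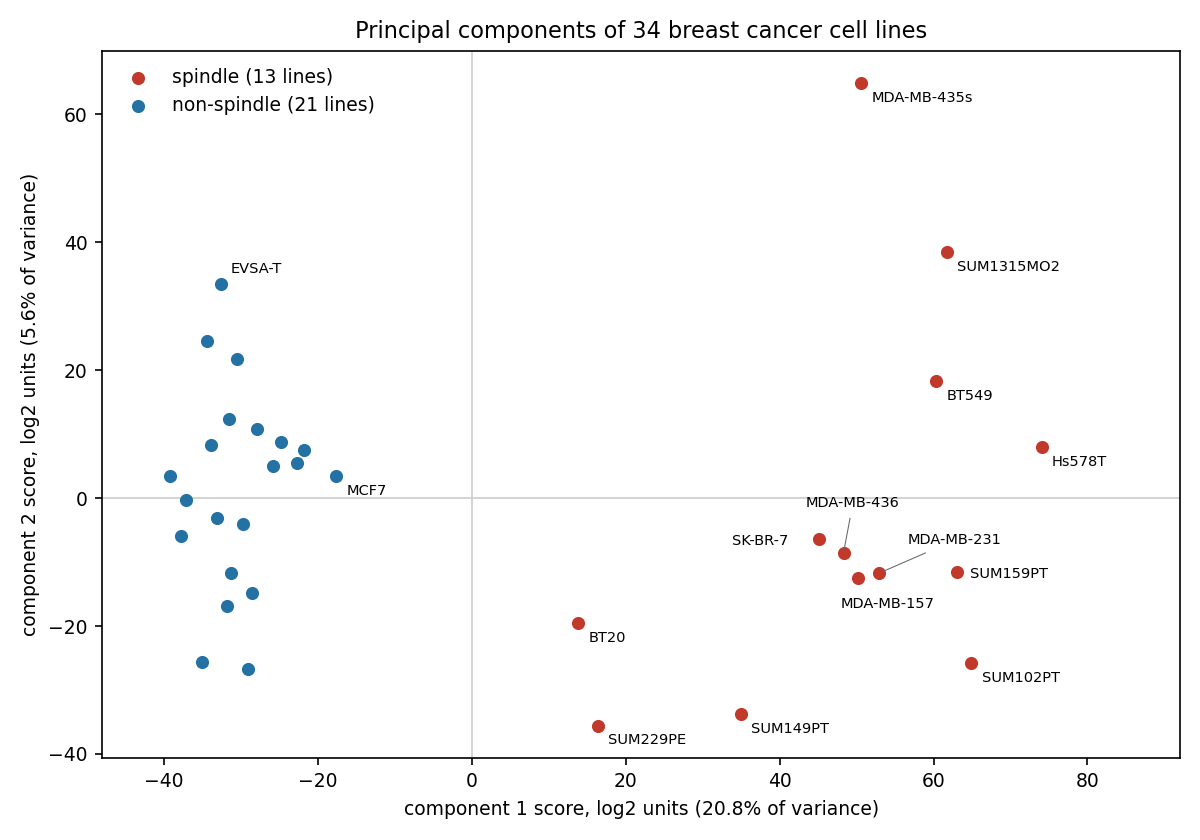
Scores of the 34 compared lines on the first (20.8% of variance) and second (5.64%) principal components of log2 values, by morphology. Every spindle line lies above 13 on the first component and every non-spindle line below -17.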

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

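The tests of the called genes and lists against random splits, the tests of scaling and of the 3' to 5' ratio on the called genes, and the count of melanocyte markers were chosen after those results were seen. Scaling and mixed RNA in MDA-MB-435s and the MMP14 probe sets were given their bounds before their test values were seen, but the comparison of MDA-MB-435s with other spindle lines was added afterwards.

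The 5 lines of unstated morphology entered no comparison, and 111 measures of theirs (22 list means and 89 genes) were set against the 34 compared lines. In 12 measures such a line was the highest of all 39, where 14.2 would be reached by chance if all lines were alike. UACC893 had a mean log2 value of 9.21 over the epithelial adhesion list (highest compared line BT483, 8.97), 9.65 over the ERBB2 amplicon list (SK-BR-3, 9.07) and 6.83 over the cadherin and catenin list (MCF7, 6.80). In the same line GRB7 was 11.87 (ZR-75-30, 10.73) and INHBB was 11.25 (BT20, 10.43). UACC812 had a mean of 10.00 over the estrogen response list (MCF7, 9.62), with SCGB2A2 at 13.13 (MPE600, 13.09) and TFF3 at 13.32 (MDA-MB-175VII, 13.18). DU4475 had a mean of 6.90 over the neural and neuroendocrine list (MDA-MB-436, 6.73), with TCF4 at 9.65 (BT549, 8.74), INHBB at 11.15 (BT20, 10.43) and PFKP at 11.47 (SK-BR-7, 11.29). GBP1 was 8.77 in HCC1937 and 8.07 in MDA-MB-468, where the highest compared line, SUM102PT, had 8.05.

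Between the morphologies 2232 genes and 15 of 22 lists were called. Chance can be excluded for the genes, since 1 of 100 splits, the real one, called as many and the highest of the others called 5, but for the lists 3 of 100 splits called at least 15 and the highest of the others equalled the real 15, with a median of 7, so the number of lists called at the preset correlation carries little weight. Uneven scaling did not account for the calls, of which 94.3% were kept in the same direction after trimmed mean scaling. Whether it accounts for the excess of lower genes stays open, since the answer depended on the scaling used. Of the calls, 42.7% were higher before rescaling and 51.3% after trimmed mean scaling, but 46.35% after quantile normalization and 46.95% after 75th percentile scaling. A difference in the 3' to 5' ratio was not the whole cause, since with the ratio as a covariate the differences of the called genes had a median of 0.969 times their size without it, although 73.1% kept their call. What remains open is whether morphology itself or another property that goes with it, such as luminal or basal subtype, underlies the differences.

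In MDA-MB-435s 8 of 16 melanocyte markers (MLANA, SOX10, S100B, TYR, EDNRB, GPM6B, MITF and CSPG4) were the highest of 39 lines, where 0.410 would be the number for a given line by chance, while the other 8, among them PMEL (5.44) and TYRP1 (4.79), were higher in at least 1 other line. This array had the lowest trimmed mean, but scaling did not explain the markers, since after rescaling the share of melanocyte markers highest there was 16.6 times that of leukocyte, endothelial and neural markers (10 of 16 against 2 of 53). RNA of other cells mixed into the sample stays open: the median over the epithelial list was 4.33, below the 8.07 to 9.07 of the non-spindle lines, but the bound set on these lines was not apt for a spindle line, since the other 12 spindle lines reached down to 4.45. A melanocytic identity of the cells is a candidate explanation that these values allow, and only 1 of the 16 markers is in another list. A mislabelled sample was not tested and stays open, and without this line 2176 genes were called.

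MMP14 was represented by the brightest of its 4 probe sets, which was lower in spindle lines (-4.01), while its other 3 probe sets were higher (1.36, 2.75 and 1.78). Its r with the mean of the other 3 was -0.367 inside the spindle group (n = 13, permutation p = 0.216, rho = -0.190 with p = 0.535) and -0.284 inside the non-spindle group (n = 21, permutation p = 0.212, rho = -0.305 with p = 0.176). The other 3 had a mean r among themselves of 0.889 in spindle but 0.184 in non-spindle lines, so whether the brightest reads another transcript than MMP14 could not be decided. Its closest probe sets inside the groups were those of ALPP (r = 0.885), RAB25 (0.874) and CLDN7 (0.852). No biological explanation was tested for this probe set, and the direction of MMP14 stays open.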

How the results depend on the processing

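Trimmed mean scaling, alone or with an estimated correlation, and omission of the 5 off-target arrays were chosen after seeing the data. Across the alternatives, 1579 to 2466 genes were called, and every gene shared with the 2232 kept its direction. Leaving out 1 line at a time gave 1969 to 2286 calls (847 to 1108 higher, 1068 to 1350 lower) and changed no list's call. Among genes with a mean above the median, where fewer genes were tested, 532 were higher, and without the off-target arrays, with fewer lines, 776 were lower. The causes of the changes below were not tested. With an estimated correlation these lists lost their call, as adjusted p and then with trimmed mean scaling as well: estrogen response 0.0763 and 0.0509, basal 0.179 and 0.176, ERBB2 amplicon 0.40 and 0.361, TGF-beta 0.183 and 0.140, proliferation 0.467 and 0.439, interferon 0.248 and 0.269, cholesterol 0.204 and 0.140, and oxidative phosphorylation 0.416 and 0.361. Over their other alternatives these 8 lists were called, except proliferation with fry (0.142) and TGF-beta among the genes above the median (0.143). There the EMT list, tested without SNAI2, ZEB1, ZEB2, TCF4, SNAI1 and TWIST1, also lost its call (0.865), and the neural list gained one (0.0349). Hypoxia gained a call with quantile normalization (0.0461). Epithelial, mesenchymal, luminal, matrix, actin and inflammatory lists were called in all alternatives. Melanocyte and endothelial lists had too few genes above the median to be tested. MMP14 was reversed as the mean of its probe sets (0.47, adjusted p = 0.176). Of 80 called genes named, 17 lost the call in at least 1 of their alternatives (77 of 4063 gene values in all), and 25 values of genes not called gained one. The covariate ended the calls of UQCRC2 (adjusted p = 0.209), SCG5 (0.0778), TUBB3 (0.0712), MITF (0.0648), EGLN3 (0.0622) and LAPTM5 (0.0542), and the Wilcoxon test those of SCG5 (0.197), IL32 (0.146), RAC2 (0.118), CSPG4 (0.115), LAPTM5 (0.0809), UQCRC2 (0.0579) and EGLN3 (0.054). With the covariate the differences were -0.50 for UQCRC2, 1.66 for SCG5, 0.49 for TUBB3, 0.77 for MITF, -1.06 for EGLN3 and 0.82 for LAPTM5. PMEL was not called in 25 of 45 alternatives (highest 0.169 without the off-target arrays). Calls that turned on 1 line were those of EGLN3 (17 lines, highest adjusted p = 0.0777 without SUM1315MO2), PMEL (20 lines, 0.100 without SUM1315MO2), UQCRC2 (BT20, CAMA-1, EVSA-T, Hs578T, MDA-MB-231, MDA-MB-435s, SUM149PT and T47D, highest 0.0780 without BT20), and, gaining a call, LYVE1 (BT20, BT474, EVSA-T, MDA-MB-157, MDA-MB-175VII, MDA-MB-231, MDA-MB-435s and SUM44PE, lowest 0.0230 without MDA-MB-435s), TWIST1 (BT20, BT474, MDA-MB-134VI, MDA-MB-231, SUM44PE, SUM229PE and ZR-75-1, lowest 0.0245 without MDA-MB-231) and PSMA2 (0.0445 without MDA-MB-157). PSMA2 also gained a call as the mean of its probe sets (0.00763), TWIST1 with quantile, 75th percentile and trimmed mean scaling (0.0496, 0.0438 and 0.0409), and LYVE1 with 75th percentile scaling (0.040), trimmed mean scaling (0.031), the larger pseudocount (0.049), array weights (0.0377) and without the off-target arrays (0.042). The first component kept its difference (62.3 to 93.9) with genes scaled to unit variance, quantile normalization, genes above the median, both other pseudocounts and trimmed mean scaling, and it was not recomputed under the others. The r of CDH1 with ZEB2 in spindle lines was -0.777 with mean probe sets and -0.819 with trimmed mean scaling, and none was given with quantile normalization or other pseudocounts, where the lines clustered. Values near the pseudocount, such as CDH1 in 8 spindle lines, limit how large a difference can be measured.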

Other observations

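The test of the non-overlapping genes against CDH1 had the bounds on r written before its value was seen, and the count of spindle lines with high CDH1 was chosen after. The genes in the next paragraph were chosen after their values were seen, as the large differences outside every list.

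Among genes in no list, spindle lines had higher values of the secreted factor IGFBP7, the collagen hydroxylase P3H2, the Ras-induced membrane protein TMEM158, the Kunitz inhibitor TFPI2, the actin bundler FSCN1, and the glutathione enzymes GPX1 and GSTP1, all of them called. GPX1 differed by 4.05 (adjusted p = 0.00309) and GSTP1 by 3.43 (adjusted p = 6.6e-05), FSCN1 by 3.66 (adjusted p = 3.1e-08) and IGFBP7 by 4.22 (adjusted p = 5.3e-05). Lower values were those of IGFBP5 (-4.38, adjusted p = 0.00111), the aldehyde dehydrogenase ALDH3B2 (-4.29, adjusted p = 3.4e-09), the mitochondrial carrier UCP2 (-4.05, adjusted p = 4.2e-06) and the calcium-binding EFHD1 (-4.08, adjusted p = 7.5e-10). No enrichment was tested for these genes.

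The 5 lines of unstated morphology had CDH1 between 9.63 and 11.64 (median 11.18), VIM between 4.71 and 7.35 and ZEB1 between 4.18 and 5.17. HCC1937 had CAV1 at 10.09 and MSN at 9.04, above every non-spindle line, and SNAI2 at 7.33, and MDA-MB-468 had MSN at 8.64. EGFR was 11.94 in MDA-MB-468, 9.14 in HCC1937 and 8.78 in UACC893. KRT5 was 10.12 in DU4475 and 9.40 in MDA-MB-468, and KRT19 was 4.19 in DU4475 and 6.41 in HCC1937. ERBB2 was 12.84 in UACC893 and 12.59 in UACC812, and ESR1 was 10.36 in UACC812. FOXA1 was 7.19 to 9.17 in the 5 lines.

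A hypothesis was that loss of CDH1 decides the values of the 22 genes without overlap between the morphologies. Chance can be excluded for the count, since 1 of 100 splits, the real one, gave as many and the highest of the others was 0. Inside the 13 spindle lines their median absolute r with CDH1 was 0.490, between the bounds set for either outcome, so r did not decide it. The 27 called epithelial genes other than CDH1 had a median signed r of 0.799, and TJP3 and MYO5C were in both sets. Neither set was checked for clusters of lines, and 8 of the 13 lines had CDH1 under the pseudocount. The selection may also have limited r, since it left out genes whose value in any spindle line reached the non-spindle range. Of the 22 genes, 8 had an absolute r above 0.6, and FOXA1 was 6.57 to 7.43 in the 3 spindle lines with CDH1 above the non-spindle median, against a mean of 5.48 over all spindle lines. By their selection all 22 genes were on the spindle side in these 3 lines and on the non-spindle side in SK-BR-3 (CDH1 at 3.42), so their side is no test of CDH1. The CDH1 values took no part in the selection. For these 22 genes only, the spindle side thus occurred in 3 lines without loss of the CDH1 messenger. In SK-BR-3 low CDH1 occurred without the spindle side. How far CDH1 sets the size of the values stays open. E-cadherin protein was not measured.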
